A study of Mus musculus with 12 samples.

How the data were processed

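Poly-A-selected RNA from ventricular tissue of male C57BL/6N mice, with the atria removed, was sequenced in 12 libraries, per the labels' protocols. The deposited table holds read counts per gene, not normalized, for each library. Per the submitters' processing notes, cutadapt 1.15, HISAT2 2.0.5 and HTSeq 0.9.1 were used with the genome build mm10. These notes do not tie each tool to a step. The annotation release and the strand setting of the counting are not given in the sources used here, and the library protocol in the labels names no step that marks strand, so genes that overlap on opposite strands, and near-identical copies, are uncertain in their values. Among named genes, Csf1r shares 15.1% of its exon bases with Hmgxb3 on the opposite strand, and Pfkfb2 shares 17.4% with Gm29427 on the same strand. A further 12 per-sample FPKM columns were not used. The authors' deposited table of their own comparison gives group means of scaled counts (a signal, equal to counts divided by size factors and averaged), log2 fold changes, p-values and adjusted p-values. Its adjusted p-values equal a Benjamini-Hochberg adjustment over its 33183 genes with a p-value.

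The library name in the description label set each sample's group, because titles and treatment labels give the opposite condition for every sample. Columns of the count table were matched to samples by the same library names. No library was assigned to a condition from its values. The groups, the test, the named-gene rule, the gene lists and the alternatives were fixed before the data were examined, except where the text says that a choice came afterwards.

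From the counts, genes were kept with edgeR's filterByExpr (15114 of 54949 features), scaled by TMM and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), HF-named against con-named, two-sided, with group as the only term. All adjusted p-values of genes are from this test with Benjamini-Hochberg adjustment over all genes tested, at a threshold of 0.05, unless another tool is named. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. CPM values (edgeR) are counts scaled to the TMM-adjusted library size, given as mean ± SD. Of the tested identifiers, 14904 (98.6%) were found in GENCODE M21 on mm10 (GRCm38), which gave coordinates, exon lengths and GC content. The table also holds 503 unnamed assembled features, of which 205 were tested and 27 called, and these stayed in the counts but were not named.

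The genes named were Angptl4; the 8 largest rises and 8 largest falls among called genes with a mean of at least 1 CPM, leaving out unnamed models, pseudogenes and receptor segments; the 3 genes of smallest p in each pathway list with at least 3 calls, otherwise the 1 of smallest p; and the 2 most abundant measured genes of each marker list. This gave 93 genes. Among these, 1 is not reported here. Other members of the lists are named where a list had few calls, and were chosen after their values were seen. There were 19 pathway lists and 14 marker lists, and the 30 with at least 5 measured members were tested with camera (limma) on log2 CPM (prior count 2) at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation, fry and an exact permutation of list scores over all 924 splits of the libraries were run beside it, the exact permutation for all lists except the high-fat-diet list being added after the data were seen. Differences of single values per library were tested by the same exact permutation.

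Before use, the steps were tested on simulated data drawn from these libraries' means, dispersions and totals. For this comparison, on 14963 genes, the test recovered 46% of genes changed 1.25-fold, 69.4% of those changed 1.5-fold, 92% of those changed 2-fold and 100% of those changed 4-fold, and 7 of 156 calls were false (4.49%). Only 200 genes were given a change, while 2016 were called in the real data. The adjustment depends on the number of changed genes, so these rates need not hold there. The list of calcium handling and contraction, shifted by 0.25 on the log2 scale, was called, as was 1 of the 28 other lists. These others hold the cardiomyocyte markers, which share 8 genes with the shifted list, so this is no rate of false calls. Genes were simulated independently, so the correlation between members of a list was not covered.

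Alternatives were size factors (RLE) or library totals in place of TMM, no filter beyond 1 count, a filter of 1 CPM in 6 libraries, the replicate number as a block, each library left out in turn, limma-voom and DESeq2 1.42.0. Added after the data were seen were the gene lists under RLE and without a filter, an offset for exon length and GC content (splines with 5 degrees of freedom), a fit without mitochondrial transcripts and unnamed features, and camera on gene ontology terms deposited with the counts. Totals of 14443186 to 22048689 counts per library put a floor of 3 counts at 0.142 to 0.217 CPM in a library. Such floors cover counting error only.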

Results

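RNA of ventricular tissue from male C57BL/6N mice was sequenced in 12 libraries. The study compared a model of heart failure with preserved ejection fraction (HFpEF), in which the heart fills poorly although its pumping fraction is kept, with control mice. The model combined dietary fat with L-NAME, an inhibitor of nitric oxide synthases, at 0.5 g/L in the drinking water, starting at 8 weeks of age and lasting 5 weeks. The labels contradict each other for all 12 samples: those titled as HFpEF, with the diet and inhibitor as treatment, carry the library names con-1 to con-6, and those titled as control, on normal diet, carry HF-1 to HF-6. The groups are therefore called con-named and HF-named after the library names, fold changes are HF-named over con-named, and which of the 2 groups was treated is left open. The labels hold 6 samples per group, while the design text speaks of 5 per group for this assay. The labels do not state that each library came from a separate mouse, so p-values measure the spread between these samples.

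Total counts per library ran from 14443186 to 22048689, with a mean of 17049507 ± 1557155 in the con-named and 17348528 ± 3068215 in the HF-named libraries (SD, n = 6 each; exact permutation test, two-sided, p = 0.8355). Mitochondrial transcripts took 22.4 ± 1.10% of the counts in the con-named and 25.2 ± 1.19% in the HF-named libraries (SD, n = 6 each; exact permutation p = 0.004329). The first principal component, with 22.9% of the variance, had negative scores in all 6 con-named and positive scores in all 6 HF-named libraries. Libraries of a group differed by far more than sampling noise in all 30 pairs, with a chi-square per degree of freedom of 4.02 to 16.3, so no pair was the same library counted again with sampling noise alone, which does not show that the libraries came from separate mice.

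The comparison of the groups asks which ventricular transcripts differ between the HFpEF model and control. Among the largest rises in the HF-named libraries were those of Edn3, which encodes endothelin 3 (3.14-fold), the stress-induced cytokine gene Gdf15 (3.09-fold) and Mthfd2, a mitochondrial folate enzyme (2.74-fold). The cyclic nucleotide phosphodiesterase gene Pde11a, the potassium channel gene Kcnc1, the sodium channel subunit gene Scn4b and the melanin synthesis gene Dct rose by 2.63, 2.62, 2.30 and 2.15 times. The largest fall was in Cyp1a1, an enzyme gene known as a target of the aryl hydrocarbon receptor, which had 0 counts in all 6 HF-named libraries. The growth factor gene Nrg1 (log2 fold change -1.80), the fetuin gene Ahsg (-1.77), the secretoglobin gene Scgb1c1 (-1.64), the dopamine receptor gene Drd2 (-1.44), the kinase gene Sbk3 (-1.39), the imprinted non-coding RNA H19 (-1.34) and the sodium-proton exchanger gene Slc9a3 (-1.29) also fell. Of 15114 genes tested, 2016 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1252 higher and 764 lower (62.1% higher). Scaling by library totals alone turned that split to 15.8% higher, with 483 higher and 2582 lower, because the median log2 fold change of all genes then moved from -0.01 to -0.13. Most changes were small, with a median absolute log2 fold change of 0.29 among the genes called, and 65 genes changed by at least 1 on the log2 scale (29 higher, 36 lower).

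Among the genes that rose, Scn4b (ENSMUSG00000046480, protein-coding, mm10 chromosome 9, 45138395 to 45154152) went from 39.1 ± 7.66 to 90.1 ± 15.6 CPM (counts scaled to library size; SD, n = 6 each), with a log2 fold change of 1.20 (SE 0.13, edgeR adjusted p = 0.000162). All 6 HF-named libraries lay above every con-named library for Scn4b, Gdf15, Mthfd2, Pde11a and Dct, and 4 of 6 did for Edn3. Edn3, Gdf15 and Kcnc1 were close to the detection limit in the con-named libraries, at 0.826, 0.655 and 0.650 CPM, where 3 counts correspond to between 0.145 and 0.200 CPM.

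Among the genes that fell, Scgb1c1 (ENSMUSG00000038801, chromosome 7, 140845547 to 140846769) had the smallest p of all genes tested, with 10.2 ± 1.44 CPM in the con-named and 3.25 ± 0.332 CPM in the HF-named libraries (SD, n = 6 each; log2 fold change -1.64, SE 0.11, edgeR adjusted p = 9.3e-07). Cyp1a1 (ENSMUSG00000032315, chromosome 9, 57687928 to 57703824) had 20 to 86 counts in each con-named library, 317 in all, and its 0 counts in the HF-named libraries correspond to a level at least 98.9-fold lower, against a floor of 3 counts over the group. All 6 HF-named libraries lay below every con-named library for Cyp1a1, Nrg1, Ahsg, Scgb1c1 and Slc9a3, and 5 of 6 did for Drd2, Sbk3 and H19. The call on Drd2 was lost in 5 of the 12 fits that left out 1 library (without con-named replicates 4 or 5, or HF-named replicates 1, 2 or 4; edgeR adjusted p up to 0.0694), while the other genes named among the largest rises and falls passed in all 12. Complete separation arises by chance in 0.216% of splits for a gene that was not chosen by its change, whereas these genes were chosen for theirs, so it is no test of them.

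**Figure D1:**
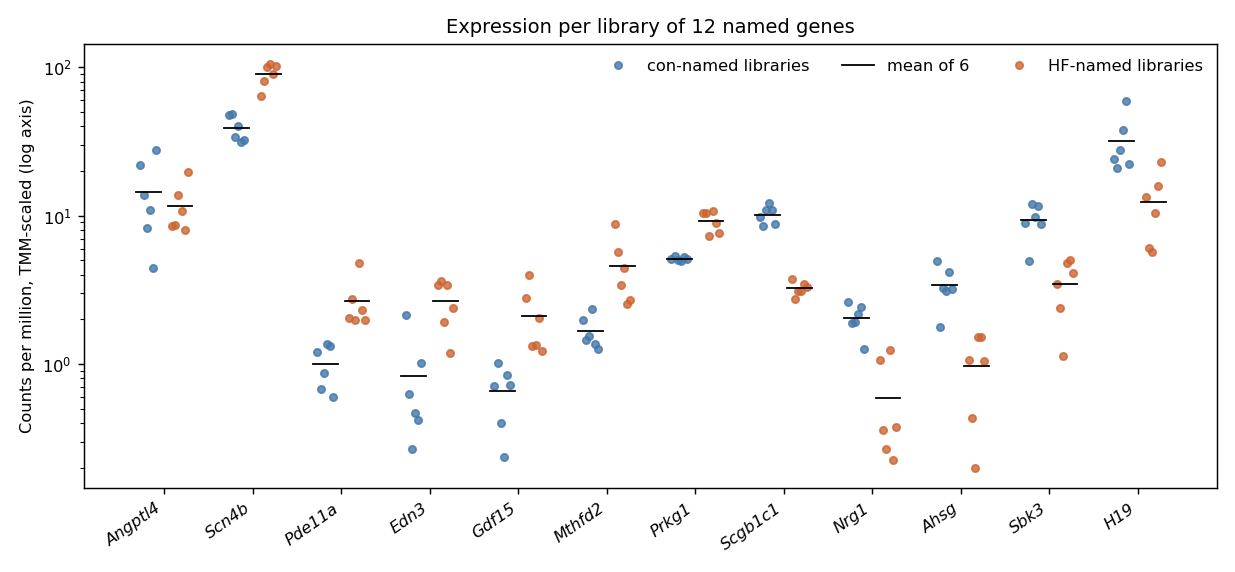
TMM-scaled CPM on a log axis for 12 named genes, with 1 point per library (6 con-named, 6 HF-named) and a bar at each group's mean. The points of both groups overlap for Angptl4, at 14.5 CPM in the con-named and 11.6 CPM in the HF-named libraries, and are fully apart for Scn4b and Scgb1c1.

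Angptl4, the secreted lipoprotein lipase inhibitor named in the series title, did not pass the test. Its level was 14.5 ± 8.66 CPM in the con-named and 11.6 ± 4.54 CPM in the HF-named libraries (SD, n = 6 each), a log2 fold change of -0.31 (SE 0.34, edgeR adjusted p = 0.60). The gene (ENSMUSG00000002289) lies on the minus strand of chromosome 17, 33773750 to 33781830 in mm10. No HF-named library lay outside the range of the con-named ones, which ran from 4.47 to 27.5 CPM. Estimates ranged from -0.54 without HF-named replicate 6 to -0.03 without con-named replicate 6 when each library was left out in turn, and the gene passed in none of these fits.

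Part of the genes of fatty acid use rose in the HF-named libraries. Of 15 measured genes of the high-fat-diet and PPAR-alpha response, 8 rose and 0 fell, and 9 rose when adjusted over the list alone. Among them were the acyl-CoA thioesterase gene Acot2 (107 ± 22.3 to 189.8 ± 24.2 CPM, log2 fold change 0.83) and the dienoyl-CoA reductase gene Decr1 (445 ± 39.4 to 632 ± 69.0 CPM, 0.51). Reads of Acot2 and Acot1, both higher, can be shared because the genes are near-identical copies. Of 16 mitochondrial fatty acid oxidation enzymes, 9 rose and 1, the electron transfer flavoprotein subunit gene Etfb (-0.24), fell. Adjusted over the list alone, 10 rose and 1 fell. Hadha, of the trifunctional protein, went from 1448 ± 151 to 1997 ± 201 CPM (0.46), Cpt2, of carnitine-dependent import, from 236 ± 29.4 to 323 ± 26.9 CPM (0.45), and the short-chain acyl-CoA dehydrogenase gene Acads from 167 ± 11.2 to 207 ± 8.79 CPM (0.31). The list medians were 0.33 and 0.27, with camera adjusted p = 0.000685 and 3.2e-05 at the preset correlation, and adjusted p = 0.734 for both with an estimated correlation.

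Transcripts of the respiratory chain that are encoded by mitochondrial DNA also rose, with 6 of 13 higher and 0 lower (9 higher adjusted over the list alone, median 0.30). The complex I genes mt-Nd2, mt-Nd5 and mt-Nd6 had log2 fold changes of 0.46, 0.48 and 0.30, and camera gave adjusted p = 7.03e-05, against adjusted p = 0.734 with an estimated correlation. These transcripts make up most of the mitochondrial share of counts given above, and mt-Nd5 and mt-Nd6 overlap on opposite strands, so reads from the shared stretch cannot be assigned without strand information. Of 25 nuclear-encoded respiratory chain genes, 1 rose and 2 fell, also when adjusted over the list alone: the complex I gene Ndufs1 (0.23) against the ATP synthase gene Atp5o (-0.24) and the complex I gene Ndufb8 (-0.17). That list was not called (camera adjusted p = 0.31), but was called lower without con-named replicate 2 (0.0179) and under library totals (0.0024), and Ndufb8 was lost without con-named replicates 1 or 4 or HF-named replicate 1 (edgeR adjusted p up to 0.0548).

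Sugar and lipid synthesis genes moved in both directions. Among 20 genes of glucose uptake and glycolysis 4 rose and 2 fell, the same counts as when adjusted over the list alone. The regulatory enzyme gene Pfkfb2 rose from 47.9 ± 6.31 to 90.0 ± 21.9 CPM (0.91) and the pyruvate dehydrogenase kinase gene Pdk1 rose (0.43), while the muscle enolase gene Eno3 fell from 1464 ± 85.4 to 1089.6 ± 77.0 CPM (-0.43; camera adjusted p = 0.687 for the list). Of 18 sterol synthesis genes 4 fell and 1 rose, or 6 and 1 adjusted over the list alone. The mevalonate pathway gene Mvd (-0.41) and the sterol carrier gene Stard4 (-0.58) fell, and Insig1, which restrains sterol synthesis, rose (0.71). The list median was -0.20 with camera adjusted p = 0.0305, and adjusted p = 0.734 with an estimated correlation. The call on this list was lost without con-named replicate 2 (0.0582), con-named replicate 6 (0.0602) or HF-named replicate 1 (0.058) and under library totals (0.0595), and that on Stard4 without con-named replicate 5 or HF-named replicates 2, 4 or 5 (edgeR adjusted p up to 0.0577). Among 13 fatty acid synthesis genes, also when adjusted over the list alone, Me1 (0.52) and Acacb (0.34) rose and Acly (-0.26) fell. Acly was lost without con-named replicates 2 or 3 or HF-named replicates 2, 4 or 5 (edgeR adjusted p up to 0.0699). In branched-chain amino acid breakdown 1 of 17 genes changed, Bckdhb (-0.32), likewise when adjusted over the list alone. The camera adjusted p was 0.929 for fatty acid synthesis and 0.676 for branched-chain amino acid breakdown.

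Genes of cardiac stress and of the contractile machinery changed in part. Of 11 measured genes of hypertrophy and the fetal program 3 rose and 0 fell, or 5 and 0 adjusted over the list alone. The actin-binding repeat gene Xirp2 went from 485 ± 40.7 to 777 ± 127 CPM (0.68), the stress-responsive ankyrin gene Ankrd1 from 1109.5 ± 119 to 1565.5 ± 229 CPM (0.50), and the LIM-domain gene Fhl1 from 82.4 ± 7.45 to 107 ± 5.08 CPM (0.37). Camera gave this list an adjusted p of 0.0171, and adjusted p = 0.734 with an estimated correlation. It was lost without HF-named replicate 1 (0.0921). The natriuretic peptide gene Nppa was at 87.7 ± 23.3 and 76.3 ± 65.7 CPM and did not pass the test (log2 fold change -0.21, edgeR adjusted p = 0.776). Its estimate ran from -0.71 without HF-named replicate 1 to -0.02 without HF-named replicate 5, and 4 of 6 HF-named libraries lay below and 1 above every con-named library. In calcium handling and contraction 5 genes rose and 5 fell among 20, or 7 and 5 adjusted over the list alone. The sodium-calcium exchanger gene Slc8a1 (0.73), the ryanodine receptor gene Ryr2 (0.46) and the titin gene Ttn (0.40) rose, and the troponin gene Tnnt2 had a log2 fold change of -0.23. The Tnnt2 call was lost in 10 of the 12 fits without 1 library, all but those without con-named replicate 2 or HF-named replicate 5 (edgeR adjusted p up to 0.10). Among 12 genes of nitric oxide and natriuretic peptide signalling 1 rose and 3 fell, or 2 and 5 adjusted over the list alone. Prkg1, which encodes the cGMP-dependent kinase, went from 5.14 ± 0.156 to 9.24 ± 1.54 CPM (0.84, edgeR adjusted p = 0.000536), and the natriuretic peptide clearance receptor gene Npr3 from 25.4 ± 5.61 to 15.8 ± 4.13 CPM (-0.68). The endothelial nitric oxide synthase gene Nos3 had a log2 fold change of -0.34, a call lost without con-named replicates 2 or 5 or HF-named replicates 4, 5 or 6 (edgeR adjusted p up to 0.0612). Neither list passed camera (adjusted p = 0.687 and 0.514).

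Some matrix and angiogenesis genes were lower in the HF-named libraries. Of 29 extracellular matrix genes 3 fell and 0 rose, also when adjusted over the list alone: the proteoglycan gene Dcn (297 ± 27.0 to 234 ± 21.9 CPM, -0.35), the membrane metalloproteinase gene Mmp14 (-0.38) and the cartilage matrix gene Comp (-1.19). No collagen gene among those measured passed. Of 27 angiogenesis genes 4 fell and 1 rose, or 6 and 2 adjusted over the list alone, with the endothelial ligand genes Vegfc (-0.49) and Apln (16.6 ± 3.43 to 9.98 ± 3.53 CPM, -0.74) lower and Vegfa (0.33) higher. Camera gave adjusted p = 0.0385 for the matrix list (median -0.11), against adjusted p = 0.88 with an estimated correlation, and adjusted p = 0.00296 for angiogenesis (median -0.22), against adjusted p = 0.734 with an estimated correlation. The matrix call was lost without con-named replicates 2 or 5 or HF-named replicates 2, 4, 5 or 6 (camera adjusted p up to 0.241). It was also lost under library totals (0.297) and with replicate number as a block (0.102). The Comp call was lost without con-named replicate 5 or HF-named replicates 4 or 5 (edgeR adjusted p up to 0.0554).

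Markers of fibroblasts, endothelial cells and macrophages fell as lists. Of 10 measured genes each, 4 fibroblast, 3 endothelial and 3 macrophage markers fell and 0 rose, and 4, 5 and 5 fell adjusted over the list alone. Besides Dcn, the fibroblast marker Gsn went from 808 ± 60.9 to 662 ± 65.1 CPM (-0.29). The abundant endothelial markers Fabp4 (-0.19) and Cdh5 (-0.34) did not pass, whereas Vwf, the gene of von Willebrand factor, fell by 1.04 on the log2 scale (chosen after its value was seen). Fabp4 passed without HF-named replicate 3 (edgeR adjusted p = 0.0195), and the Cdh5 log2 fold change without that library, HF-named replicate 1 or con-named replicate 1 (edgeR adjusted p down to 0.0182), under library totals (0.0331) and in DESeq2 (0.0393). The macrophage markers Lyz2 and Csf1r had log2 fold changes of -0.39 and -0.35, and Csf1r was lost in 8 of the 12 fits without 1 library, those without con-named replicates 2, 4, 5 or 6 or HF-named replicates 1, 2, 4 or 5 (edgeR adjusted p up to 0.0781). List medians were -0.24, -0.24 and -0.25, with camera adjusted p = 0.00208, 0.00437 and 0.00271, and adjusted p = 0.734 for each with an estimated correlation. The matrix and fibroblast lists share 4 genes, and the angiogenesis and endothelial lists share 2.

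**Figure D2:**
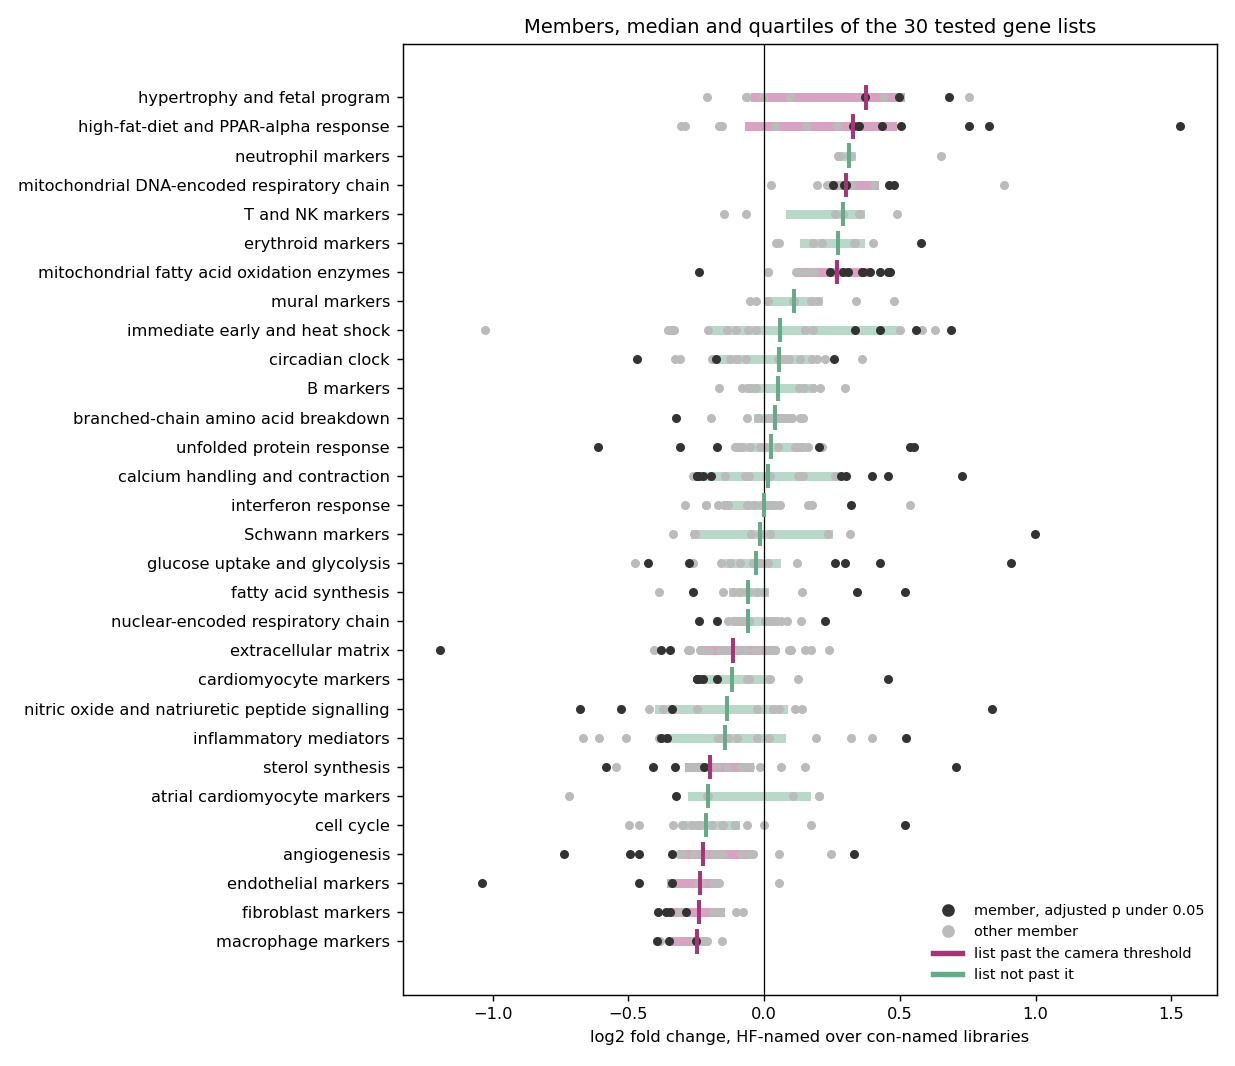
Log2 fold change (HF-named over con-named) of each measured member of the 30 tested gene lists, as points that are dark where the edgeR adjusted p was under 0.05, with a vertical tick at each list's median and a bar over its quartiles. The 4 lists called higher have medians from 0.27 to 0.37, and the 6 called lower from -0.25 to -0.11.

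Markers of other cell types did not pass camera. Of 10 cardiomyocyte markers 1 rose and 5 fell, also when adjusted over the list alone, with Myh6, the main myosin heavy chain gene of the adult mouse ventricle, at 30088 ± 1773 and 32826 ± 2129 CPM (0.13, edgeR adjusted p = 0.244). The cardiomyocyte list had a camera adjusted p of 0.0905 and was called lower without con-named replicate 2 (0.0202) and under library totals (0.0248). Of 9 mural markers, for pericytes and smooth muscle, 0 passed over all genes or adjusted over the list alone, with 0.20 for Rgs5 and 0.11 for Abcc9, the latter turning to -0.01 under library totals (camera adjusted p = 0.175). The Rgs5 log2 fold change passed without con-named replicates 2 or 6 (edgeR adjusted p down to 0.0321), in limma-voom (0.0393) and in DESeq2 (0.0208). Neutrophil (5 measured), T and NK (7) and B cell markers (10) had 0 calls over all genes or adjusted over the list alone, with camera adjusted p of 0.31, 0.31 and 0.929. The T and NK list was called higher without con-named replicate 5 (0.0274) and under library totals (0.0396). Erythroid markers had 1 rise in 8, Hba-a2, also adjusted over the list alone, and had a camera adjusted p of 0.0905. They were called higher without con-named replicate 4 (0.0215) or HF-named replicate 1 (0.00197), under library totals (0.0199), with no filter beyond 1 count (0.00783) and with the length and GC offset (0.0273). Hba-a1 and Hbb-bs (0.33 and 0.34) passed without HF-named replicate 1 (edgeR adjusted p = 0.0434 and 0.0429), and the Hba-a1 log2 fold change also with the length and GC offset (0.0417). The globin genes can share reads with near-identical copies. Schwann cell markers had 1 rise in 9, Kcna1, and atrial markers 1 fall in 7, Stard10, or 1 and 2 adjusted over the list alone (camera adjusted p = 0.881 and 0.489). Adipocyte, mesothelial and skeletal muscle lists had only 1, 2 and 3 measured members and were not tested. Of these, Cidea rose (0.33) and the mesothelial marker Gpm6a fell from 3.75 ± 0.838 to 1.60 ± 0.647 CPM (-1.22).

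Stress, inflammation and clock genes showed scattered changes. In the unfolded protein response 3 genes rose and 3 fell among 20, also adjusted over the list alone. The sensor genes Atf6 (88.6 ± 5.03 to 129.9 ± 17.3 CPM, 0.55) and Ern1 (0.54) and the co-chaperone gene Dnajc3 (0.20) rose, while Manf (-0.31), Sdf2l1 (-0.61) and Pdia6 (-0.17), of protein folding in the endoplasmic reticulum, fell (camera adjusted p = 0.489). Of 18 immediate early and heat shock genes 4 rose and 0 fell, or 5 and 1 adjusted over the list alone, among them the chaperone genes Hspb1 (0.34) and Hsph1 (0.43) and the matricellular gene Cyr61 (0.56; camera adjusted p = 0.489). Of 16 inflammatory mediators 1 rose and 2 fell, also adjusted over the list alone. The receptor gene Tlr4 rose (0.52) and the adhesion molecule genes Vcam1 (-0.38) and Icam1 (-0.36) were lower (camera adjusted p = 0.31). Rsad2 (0.32) was the 1 interferon response gene of 20 that passed, with 0 adjusted over the list alone, Mcm2 (0.52) the 1 cell cycle gene of 18, also adjusted over the list alone, and Nr1d2 (0.26), Ciart (-0.47) and Cry2 (-0.18) were the 3 of 18 clock genes, against 3 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.659, 0.31 and 0.881). Mcm2 ran against its list, as the cell cycle median was -0.21 (quartiles -0.29 and -0.11). Calls on Icam1, Rsad2, Ciart, Cry2 and Mcm2 were each lost in several of the 12 fits without 1 library, in 9, 8, 7, 10 and 4 of them (edgeR adjusted p up to 0.101, 0.106, 0.0976, 0.108 and 0.063, without con-named replicates 4, 5 and 5, HF-named replicate 2 and con-named replicate 5).

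Across the lists, 10 of 30 passed camera at the preset correlation and 0 with an estimated correlation (0 also at an unadjusted p under 0.05). The directional test of fry, which asks whether a list's genes move on balance one way, called 1, sterol synthesis (adjusted p = 0.0296), and its mixed test, which asks whether they change in either direction, called 20. An exact permutation test of each list's mean log2 CPM over libraries, two-sided, gave an unadjusted p under 0.05 for 7 of the 30 lists. Of the lists called by camera, extracellular matrix (exact permutation p = 0.288), hypertrophy (0.113) and angiogenesis (0.0563) did not reach that. After adjustment 0 lists passed (smallest adjusted p = 0.0648). That value belongs to sterol synthesis, whose exact permutation p of 0.00216 is the smallest that 924 splits can give. A single list could therefore not pass after adjustment, so the count of 0 says little. Medians and the direction given by camera differed in sign for 2 lists, interferon response and Schwann cell markers, and medians and means for glycolysis, the clock and Schwann cell markers. For fatty acid synthesis fry gave the opposite direction to camera. None of these lists passed camera at the preset correlation or the directional test of fry. Under library totals the medians of branched-chain amino acid breakdown, the unfolded protein response, the interferon response, the clock, immediate early and heat shock genes, calcium handling, mural and B cell markers turned negative, while the 10 called lists kept their direction.

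The authors' deposited table compares the same libraries and takes the con-named ones as control. Its group means equal the size-factor-scaled means of the HF-named and con-named counts, within 0.01, for 100% of the features. The authors' adjusted p is under 0.05 for 1695 genes, 1125 higher and 570 lower in HF. Of the 1674 that were also tested here, 1656 were called in edgeR too, all 1656 in the same direction, and across 15114 genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.9997. For Angptl4 the authors' deposited table gives a log2 fold change of -0.32 with an adjusted p of 0.988.

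Fold changes also followed the length of the genes' exons. The median log2 fold change went from -0.10 in the decile of genes with the shortest exons to 0.08 in the decile with the longest (Spearman correlation across 14904 genes 0.239, and -0.184 with GC content). For each library, log2 CPM was taken relative to each gene's mean over the 12 libraries. Its slope per doubling of exon length was -0.0157 ± 0.0171 in the con-named and 0.0157 ± 0.0123 in the HF-named libraries (SD, n = 6 each, exact permutation p = 0.01082). The group means are equal and opposite by this centering, so only their difference carries information. With an offset per library that removed the trend, 1533 genes were called, and 1329 of the 2016 were among them in the same direction. Among the named genes 10 calls were lost, among them Mvd, Bckdhb, Ndufs1, Ndufb8 and Gsn (edgeR adjusted p = 0.054, 0.0533, 0.0525, 0.123 and 0.0697). By camera at the preset correlation, all 10 gene lists stayed called in the same direction. With an estimated correlation 0 lists were called even without the offset.

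**Figure D3:**
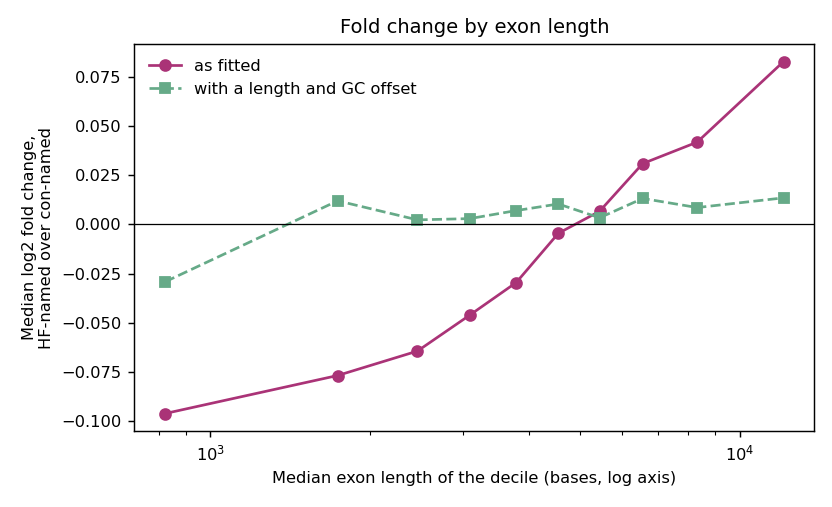
Median log2 fold change (HF-named over con-named) of the genes in each decile by total exon length, with the median length of the decile in bases on a log axis. Filled circles show the fit as made, from -0.10 to 0.08, and squares the fit with a length and GC offset per library, from -0.03 to 0.01.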

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

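In this part the tests of exon length, of cell makeup and of mitochondrial share were chosen after the results were seen, while the direction test and the splits of the libraries were planned. Within groups of 6, a single library stood apart from the others in 9 of 189 sets of values, where chance gives about 9.45. Its gap to the next library, as a share of the group's range, was 0.732 for Pde11a (HF-named replicate 4 at 4.83 CPM, the others 1.99 to 2.75), 0.647 for Slc9a3 (HF-named replicate 3, 1.26 CPM against 0.362 to 0.681), 0.639 for Pfkfb2 (HF-named replicate 2, 132.3 CPM against 72.4 to 94.0) and 0.676 for mt-Nd6 (HF-named replicate 5, 9323 CPM against 7070 to 7801). It was 0.648 for Fabp4 (HF-named replicate 3, 624.7 CPM against 418.7 to 491), 0.711 for Ighm (HF-named replicate 3, 14.9 CPM against 7.59 to 9.70), 0.658 for Pmp22 (HF-named replicate 6, 39.9 CPM against 32.6 to 35.1), 0.773 for Gpm6a (con-named replicate 5, 5.42 CPM against 3.24 to 3.74) and 0.727 for Mylpf (con-named replicate 6, low at 0.602 CPM against 1.04 to 1.21).

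The number of genes called was set against other splits of the same libraries. Of 100 splits drawn from the 462 that are possible, 1, the real one, gave as many as 2016 genes. The highest of the others gave 6 and their median was 0, so no other split drawn came near the count. In those splits the group difference adds to the spread within groups, which lowers their counts. They also cannot show whether a batch or a difference in RNA quality aligned with the groups contributed.

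The direction of the comparison rests on labels that contradict each other. If the library names were swapped and the HF-named libraries came from mice on normal diet, genes known to rise in the heart under dietary fat should have been lower there. The median log2 fold change of that list was 0.326, higher in the HF-named libraries (camera unadjusted p = 6.85e-05, exact permutation p = 0.0411, but unadjusted p = 0.22 with an estimated correlation). This median argues against swapped library names and for exchanged titles and treatment labels, but only weakly. After adjustment over the lists the exact permutation p was 0.176. Of the 15 members 8 passed, all higher, and 7 did not pass. Of those 7, Angptl4 (-0.31), Ehhadh (-0.29), Cpt1a (-0.17) and Ucp3 (-0.15) were negative, and Plin5 (0.27), Pdk4 (0.15) and Plin2 (0.04) positive. The reading may also be wrong if the diet did not raise these genes here, so the condition of each library stays open.

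Lower fibroblast, endothelial and macrophage markers could reflect fewer of all cells other than cardiomyocytes, but mural markers did not follow: the score of the 3 lists fell by 0.421 relative to the mural score (log2, exact permutation p = 0.00216). The mural list was taken as the comparator after its values were seen, so this p-value is only descriptive. Cardiomyocyte markers did not rise as a list either, with 1 of 10 higher and 5 lower (median -0.12, camera adjusted p = 0.0905). The trend with annotated exon length and GC did not account for all of the fall, since 3 of the 3 lists stayed lower with the offset. The larger mitochondrial share did not account for all of it either. The score of the 3 lists fell by 0.39 when scaled by library totals (exact permutation p = 0.00649), where the median of all genes was -0.13. It still fell by 0.338 when scaled by the counts outside mitochondrial transcripts (exact permutation p = 0.0108). With mitochondrial shares of 22.4% and 25.2%, that change of scale could remove only a small part, so most of the fall was bound to stay. A lower share of these 3 cell types, or lower expression within them, may be behind the pattern, and bulk tissue gives no test between them.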

How the results depend on the processing

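The length and GC offset, the fit without mitochondrial and unnamed features, all lists under RLE and without a filter, and most settings of the high-fat-diet list were added after the data were seen. The count of 2016 genes stayed within 1.5 times under RLE, both filters, limma-voom (2062), DESeq2 (2307), the length and GC offset (1533) and each library left out (1355 to 2550, without con-named replicate 5 and HF-named replicate 3). It moved to 3065 under library totals, by that scaling's own shift, and to 1131 (748 higher, 383 lower) with replicate number as a block. The block was planned only as an alternative, because no label says that replicate numbers mark shared litters or days. Same-numbered libraries did not deviate together (correlations -0.16 to 0.09, 0 of 6 above 0.1, and 2 of 6 matched their own number best). Genes changed by at least 1 on the log2 scale went from 65 to 210 with no filter, by adding low-count genes, and ranged from 57 to 85 with each library left out. Of the 10 lists called, 0 held with an estimated correlation and 1 with fry. For the high-fat-diet list the median stays 0.326 but the unadjusted p became 0.22 in camera with an estimated correlation. That correlation between its members was 0.684, against the preset of 0.01. Among the called lists it ran from 0.038 for sterol synthesis to 0.71 for fatty acid oxidation. The preset p-values treat members as nearly independent, which these estimates go against for most of the called lists. Camera at the preset correlation called 9 to 12 lists in the other settings. Of the 72 named genes called, 13 lost their call in at least 1 fit without a library; library totals ended 6 calls, on Vegfa, Dnajc3, Rsad2, Nr1d2, Mcm2 and Cidea, and the block 15. Signs turned only for genes that were not called: under library totals the Abcc9 log2 fold change (-0.00885) and the Igkc log2 fold change (-0.019), Lck under the offset (0.022) and limma-voom (0.019), and Ighm (0.0043), Pmp22 (0.013) and Mal (0.028) under the offset. With each library left out Lck ran from -0.19 to 0.23, Igkc from -0.20 to 0.30, Ighm from -0.22 to 0.029 and Mal from -0.068 to 0.011; the cause was not tested. Depth limits what can be said of genes near the floor of 3 counts, such as Edn3, Gdf15 and Kcnc1.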

Other observations

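All tests in this part were chosen after the data were seen. Gene ontology terms deposited with the counts pointed to groups outside the fixed lists. Of 1459 terms with 15 to 300 tested genes, 32 passed camera at the preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.939). Of 166 ribosome genes 37 were lower and 1 higher in the HF-named libraries (median -0.13, camera adjusted p = 1.77e-10, but adjusted p = 0.939 with an estimated correlation), with log2 fold changes of -0.26 for Rpl18, -0.27 for Rpl27, -0.26 for Rpl8 and -0.29 for Rpl35a. Of 44 genes of respiratory complex I, 17 were lower and 1 higher (median -0.13, camera adjusted p = 0.000781 and adjusted p = 0.939 with an estimated correlation). Of 101 Z disc genes, which anchor the thin filaments of the sarcomere, 27 were higher and 6 lower (median 0.11, camera adjusted p = 0.00131 and adjusted p = 0.939 with an estimated correlation), led by the dystrophin gene Dmd (0.54), Xirp2 (0.68), the histone deacetylase gene Hdac4 (0.47) and Ttn (0.40). Of 147 genes of ubiquitin-dependent protein breakdown 25 were higher and 1 lower, and of 26 genes of the tricarboxylic acid cycle 5 were higher and 0 lower (camera adjusted p = 0.00168 and 0.0447, each with adjusted p = 0.939 with an estimated correlation). The Z disc median turned to -0.01 under library totals, where the median of all genes was -0.13.

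Ribosome genes are short and Z disc genes longer, with median exon lengths of 2352 and 5192 bases. The length and GC trend between the library sets was therefore checked as a source of both shifts. By length alone, the median log2 fold change of all genes was -0.064 in the decile around 2461 bases. It was only -0.004 and 0.007 in the deciles around 4545 and 5438 bases, next to the Z disc length. With the offset that removes the trend, the ribosome median shrank from -0.127 to -0.067 and stayed called (camera adjusted p = 0.000533, exact permutation p = 0.013), while the Z disc median was 0.106 before and 0.112 after (camera adjusted p = 0.00383, exact permutation p = 0.00216). The trend may thus account for part of the ribosome shift. Exon length here joins all annotated exons of a gene and can exceed the length of the transcripts expressed. The offset may therefore correct too little, and it cannot show whether the trend is the whole source of the ribosome shift. The Z disc median did not shrink with the offset, but at its exon length there was almost no length trend to remove. That near absence itself argues against the length trend as the whole source of the Z disc median, and the offset adds little to it. Complex I did not pass with the offset, and 8 of the 32 terms did, all 8 in the same direction. RNA quality was not measured in the files used, so a difference in RNA integrity between the library sets stays open, as does a biological difference.

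Other members of the groups around Cyp1a1 and around Gdf15 and Mthfd2 were looked at as well. Besides Cyp1a1, 4 other known targets of the aryl hydrocarbon receptor were measured, of which Nqo1 was higher (0.26), Cyp1b1 lower (-0.62), and Ahrr and Tiparp did not pass (0.30 and 0.16; exact permutation p = 0.755 for the mean of the 4). Besides Gdf15 and Mthfd2, 18 other genes of the amino acid response and one-carbon metabolism driven by ATF4 were measured, of which 1, Aldh1l2, was higher (0.56) and 0 were lower (exact permutation p = 0.277). The cold-inducible RNA-binding protein genes Cirbp and Rbm3 were both lower, from 70.3 ± 3.59 to 54.2 ± 2.66 CPM (-0.37) and from 52.1 ± 4.01 to 37.6 ± 3.37 CPM (-0.47; SD, n = 6 each; edgeR adjusted p = 0.000607 and 0.000669).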
